A study of Caenorhabditis elegans with 3 samples.

How the data were processed

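H3K4me3 ChIP-seq was made from whole wild-type nematodes in 3 groups of 1 library each, namely a control, SMX-exposed F11 and non-exposed F14'. Per the labels' protocols, worms were grown at 20 °C on plates seeded with Escherichia coli OP50, fixed for 30 min in 2% formaldehyde, sheared to fragments of 200 to 800 bp and precipitated with an antibody against H3K4me3. The SMX dose is not given in the sources used here. The labels call F14' the first progeny raised without the drug. They also number it as generation 14 with 11 exposed generations, and the generations between are not described in the sources used here.

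The submitters' processing notes name Bowtie2 2.1.0, MACS 1.4.0rc2 and the genome build ce10. The data used were 1 annotated peak table for F11 and 1 for F14', each peak called per sample and not on pooled samples. Per the file headers, each peak has a count of tags, a fold enrichment, a score equal to -10 times the base-10 logarithm of its p, a summit, and an assigned gene with its class and distance. The tag counts are whole numbers that the authors deposited without normalization. The deposited fold is a ratio over the caller's background, and the deposited score is used to rank or filter peaks within its own table and to compute the background behind each peak, which is set side by side between the tables. The F11 table also gives the authors' FDR in percent, which MACS obtains by exchanging ChIP and control. The F14' table was used without an FDR. The control library has no table here and was not analysed by itself.

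Rows were collapsed to unique intervals, which gave 95 F11 peaks from 103 rows and 639 F14' peaks from 1025 rows, since 1 peak can be listed with several genes. The deposited distance to a transcription start equals that from the peak centre within 0.5 bp. The weakest peaks had a p of 0.00095 in F11 and 0.001 in F14', and 3100 was the usual ceiling of the score. Depth can be judged only inside peaks, and the background computed from tags and p had a median of 251 tags per kb in F11 and 235 in F14'. That background is the Poisson mean at which the peak's tags have the deposited p. It was compared with the peak's own tags, plus the median background over the rest of 10 kb, divided by 10 kb.

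Chromosome lengths were taken as the highest coordinate of any peak or gene in both tables, so all coordinates are ce10. Gene names were matched to a RefSeq gene table of assembly WBcel235, another build, from which no coordinate is printed. It served for names, gene order and, for binning only, gene length. In F11 95 of 100 RefSeq identifiers matched, and in F14' 913 of 923. Unmatched identifiers stayed in the peak counts and left the gene counts.

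Overlap of peaks required at least 1 bp and was set beside 10000 random placements of the F11 peaks. Shares carry exact Clopper-Pearson 95% intervals. Each of 25 gene lists, and in a descriptive screen each of 106 name prefixes with at least 20 members, was counted among peak genes and placed among 10000 random lists matched on gene length in 10 bins. Percentiles take ties at their middle and describe these libraries only. No p-value was computed, because each group has 1 library. As a check of the code, 30 of 30 overlaps planted on F14' peaks were found, an outcome fixed by construction. With 800 random peak genes among 46926 genes, 1 of 100 random lists of 300 genes lay above the 95th percentile. So did 100 of 100 such lists with 15 peak genes added. Clustered gene families, genes that share a peak and lists of other sizes were not simulated, so these values do not test the percentiles of such lists.

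Genes are named by a rule set before the data were examined. It takes per sample the 10 peaks with the highest fold and the 10 with the smallest p, ties by fold. It adds the first 20 genes with a peak in both tables by mean rank of fold, and up to 4 members of each list per sample with the highest fold. Other genes named were chosen after their values were seen, namely those of the 5S rRNA cluster and of the name-prefix screen. The alternatives were stricter scores, an FDR limit, a fold limit, merging within 1 kb, leaving out mitochondrial peaks, covered length in place of peak number, other overlap rules, distances of 1 and 3 kb, and other backgrounds for lists. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.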

Results

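Trimethylation of lysine 4 on histone H3 (H3K4me3), a mark found around the starts of active genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole wild-type Caenorhabditis elegans. The 3 libraries came from a control grown without drug, from nematodes exposed to the sulfonamide antibiotic sulfamethoxazole (SMX) for 11 generations (F11), and from progeny of that line raised without the drug, labelled F14'. Exposure lasted 6 days in each generation. Each group had 1 library, so no difference below has a replicate check, no p-value across peaks or genes was computed, and intervals cover counting error only. The total depth of each library is not given in the sources used here. The tables list tags inside peaks, from 346 to 31515 per peak in F11 and from 280 to 44316 per peak in F14'.

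The comparison of F11 with the control asks where the mark was higher after 11 exposed generations. The generation of the control is not given in the sources used here, so exposure cannot be told apart from generations in culture. The F11 table held 95 peaks that covered 227 kb. The peak with the highest fold lay near the start of Y14H12A.1 (chromosome II, 3994178 to 3995295, ce10; fold 8.46, 1719 tags), followed by F52G2.3 (chromosome IV, 13548903 to 13550025; fold 5.78, 5247 tags). Next came peaks assigned to the chemoreceptor gene srh-245 (fold 5.25), pes-10 (5.08), gmeb-3 (4.79), the MYST-family histone acetyltransferase gene mys-2 (4.72) and the C-type lectin gene clec-135 (4.63). T13G4.1 (4.49), C34E11.9 (4.39) and Y71A12B.12 (4.34) completed the 10 highest. The mys-2 peak was classed as intergenic and was centred 9559 bp from the start of that gene. The fold, p and tags of every peak are the authors' own values, and so are the gene names, which depend on the table. At 9 of the 95 F11 peaks and 13 of the 639 F14' peaks, the peak centre lay nearer to the start of another gene listed in either table than to that of the assigned gene. The region assigned to srh-245 in F11 (2409 bp from its start) is assigned to srh-246 in F14' (554 bp from the F11 peak centre), and the pes-10 region to lgc-35, whose start lies 7360 bp away against 2812 bp for pes-10.

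Many F11 peaks were shallow. The median fold was 2.02, 44 of the 95 peaks lay under a fold of 2, and 4 reached a fold of 5. The 10 smallest p-values belonged to peaks at C34E11.9, anr-53, Y14H12A.1, the locus shared by Y75D11A.1, ZC190.9 and linc-64, pes-10, the chemoreceptor gene srj-9, the neuropeptide gene nlp-38, T20H12.1, Y73B6A.1 and Y54F10AM.8. The region assigned to C34E11.9 (chromosome X, 11785187 to 11789965, intergenic) held 31515 tags. It was the only F11 peak with a false discovery rate (FDR) of 0% in the authors' deposited table. The other 94 peaks, Y14H12A.1 and F52G2.3 included, had an FDR of 100%. With an FDR of at most 5%, 1 peak remained.

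The comparison labelled F14' against control asks where the mark was high in unexposed descendants. The F14' table held 639 peaks covering 1436 kb, and its highest fold was again at F52G2.3 (chromosome IV, 13548896 to 13550061; fold 38.9, 6275 tags). The dynactin subunit gene dnc-6 (fold 29.9) and the F-box gene fbxa-55 (27.9) came next. They were followed by Y106G6H.9 (18.9), T23B5.6 together with C26H9A.3 (18.9), Y14H12A.1 (18.4) and the poly(A) polymerase gene pap-1 (18.4). A cluster of piRNA genes headed by 21ur-467 (17.5), T28H10.2 (17.5) and vha-19 (17), which encodes a proton pump subunit, completed the 10 highest. Intergenic peaks among these were those of dnc-6 (centred 3811 bp from its start), fbxa-55 (4616 bp), Y106G6H.9 (4916 bp) and pap-1 (4695 bp). The median fold was 2.3, and 97 peaks reached a fold of 5. R57.2 had the smallest p (27510 tags, fold 5.87). The other 9 of the 10 smallest p-values, taken in order of fold at 1 ceiling score of 3100, belonged to the first 9 of the genes with the highest fold.

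The backgrounds behind the folds and p-values of the tables differed. MACS derives a peak's p from its tags and a local background, so that background can be computed back from both. In F14', 35 peaks had at least 2000 tags and a p under the ceiling. At the ceiling lay 69 F14' peaks, those of F52G2.3 and dnc-6 among them, against 1 in F11. These were left out, which removes peaks whose background is low for their tags. The computed background was set against a density over 10 kb, built from the peak's own tags and the median background for the rest. That density is called own tags over 10 kb below. Tags outside peaks are not listed, so this density was not measured. At 34 of the 35 peaks the background lay within 25% of it, with a median ratio of 0.993. The exception was the 5S rRNA gene cluster (rrn-4.1 to rrn-4.15), with a ratio of 2.25. In F11, 4 of 11 such peaks lay within 25%, the median ratio was 1.51, and F52G2.3 reached 5.90. Over whole peaks, tags were a median of 1.19 times the computed background in F11 and 1.23 times in F14'. In F11 they were 1.06 times that background at F52G2.3 and 1.64 times at Y14H12A.1, against deposited folds of 5.78 and 8.46. The deposited fold need not be a measure over the whole peak, so this gap does not show an error in either value. The F14' table also has no FDR column. Its folds are therefore given below as folds over the background used for that table, and the numbers of F11 and F14' peaks are not compared as a change in the mark.

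**Figure D1:**
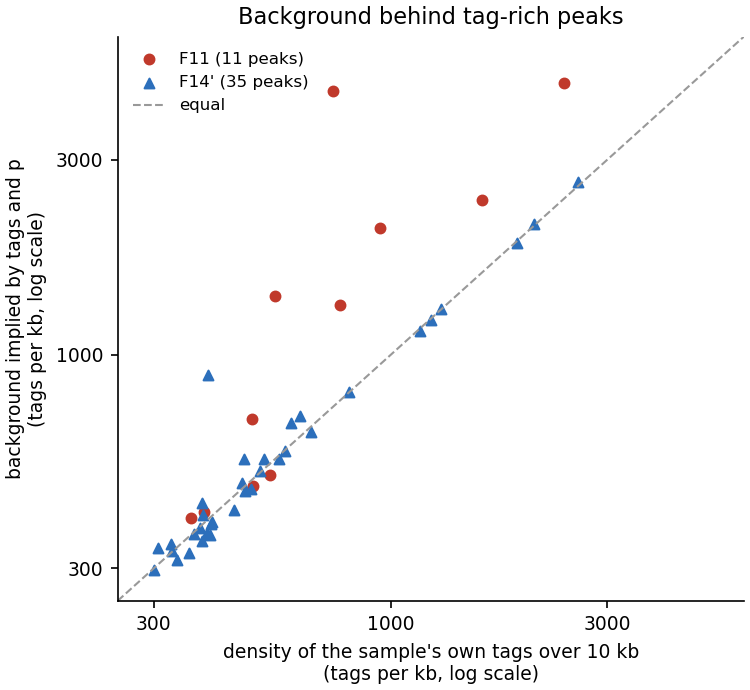
Background implied by tags and p (y axis, tags per kb, log scale) against own tags over 10 kb (x axis, tags per kb, log scale), 1 point per peak with at least 2000 tags and a p under the ceiling. The x value was built from the peak's own tags and the median background over the rest of 10 kb. The 35 F14' peaks lie along the line of equality except the 5S rRNA cluster, while 7 of the 11 F11 peaks lie above it by more than 25%.

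In both tables peaks were sparse on the X chromosome and, pooled over chromosomes, in the middle 33% of chromosome length. The middle part held 11 of 95 F11 peaks (11.6%, exact 95% binomial interval 5.92 to 19.8%) and 111 of 639 F14' peaks (17.4%, 14.5 to 20.5%). For F11 this held for the pooled share and not for each chromosome, as chromosome IV had 4 of 13 peaks there (30.8%, 9.09 to 61.4%). At a score (-10 log10 p) of at least 100 the pooled F11 share was 6 of 27 (22.2%, 8.62 to 42.3%), an interval that holds the share expected from length. The X chromosome, 17.5% of the length considered, held 9.47% of F11 peaks (4.42 to 17.2%) and 8.92% of F14' peaks (6.83 to 11.4%). Chromosome II, 15.2% of the length, held 29.5% of F11 peaks (20.6 to 39.7%), among them Y14H12A.1, pes-10, clec-135 and age-1, and 18.5% of F14' peaks (15.5 to 21.7%). Chromosome V, 20.9% of the length, held 25.3% (16.9 to 35.2%) and 24.7% (21.4 to 28.3%). Among the 95 F14' peaks with the smallest p, the shares rose to 27.4% in the middle part (18.7 to 37.5%) and 17.9% on the X chromosome.

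**Figure D2:**
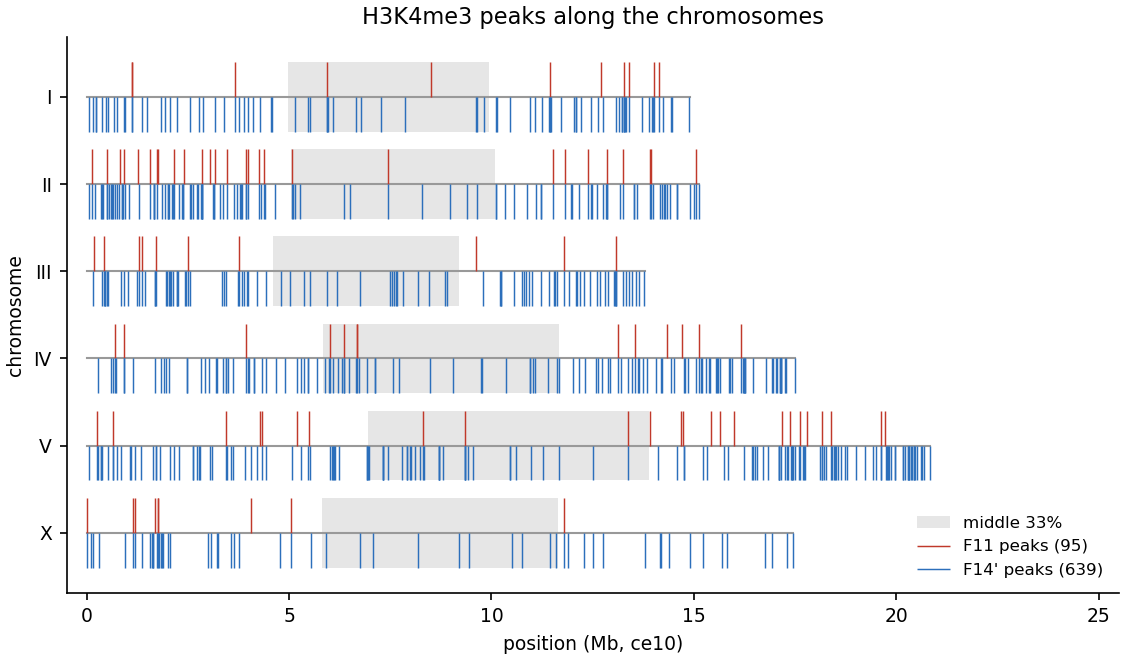
Positions of the 95 F11 peaks (upper ticks) and the 639 F14' peaks (lower ticks) along the chromosomes (x axis, Mb on ce10; y axis, chromosome), with the middle 33% of each shaded. The shaded parts hold 11 F11 and 111 F14' peaks.

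The authors' annotation placed 40 of 95 F11 peaks (42.1%, 32 to 52.7%) and 384 of 639 F14' peaks (60.1%, 56.2 to 63.9%) in promoters, all within 2 kb of a transcription start. Promoter peaks included F52G2.3, Y14H12A.1, clec-135 and age-1 in both tables. Upstream peaks made up 25.3% of F11 and 20.7% of F14' peaks, and intergenic peaks 28.4% and 13.1%. Intron peaks, such as that of the calcium sensor gene stim-1, were 2 of 95 and 21 of 639. Peaks assigned to piRNA genes alone numbered 7 in F11 and 30 in F14', and 28 of the latter lay on chromosome IV, where most piRNA genes are found. Where peaks of the tables overlapped, the annotation differed in class at 10 of 54 pairs, and 8 of these were promoters in F14' and another class in F11. Among the 95 F14' peaks with the smallest p, 35.8% were promoter peaks.

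Setting the tables side by side asks whether regions marked after exposure were also marked in unexposed descendants. Of the 95 F11 peaks, 53 (55.8%, 45.2 to 66.0%) overlapped an F14' peak by at least 1 bp. All of the 19 F11 peaks with the highest fold did so, from Y14H12A.1 and F52G2.3 to M01E5.1, a gene whose F11 peak had a fold of 3.29. Random placement of the F11 peaks on their own chromosomes gave a mean of 2.94 overlaps and at most 11 in 10000 draws. Shared F11 peaks had a median fold of 2.43 and the 42 unshared ones 1.86. The highest unshared F11 peak, a peak at Y73B6A.1, had a fold of 3.11. The highest unshared F14' peak was that of dnc-6. At the 54 overlapping pairs the tags per kb of F14' were a median of 1.03 times those of F11. At F52G2.3 the tags were 5247 and 6275 while the folds were 5.78 and 38.9. At Y14H12A.1 the tags were 1719 and 1734 while the folds were 8.46 and 18.4. Both tables are labelled as set against 1 control library, which could not be split. If both were, part of the excess over random placement may come from that control. The F14' background was not shown to be the control, however. Without it, an F14' peak shows only dense tags in that library, which the control may share. The overlap therefore does not show that the mark was raised over control in F14'. Among the 95 smallest p-values of F14', 12 F11 peaks found an overlap, against a mean of 0.514 in random placement.

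**Figure D3:**
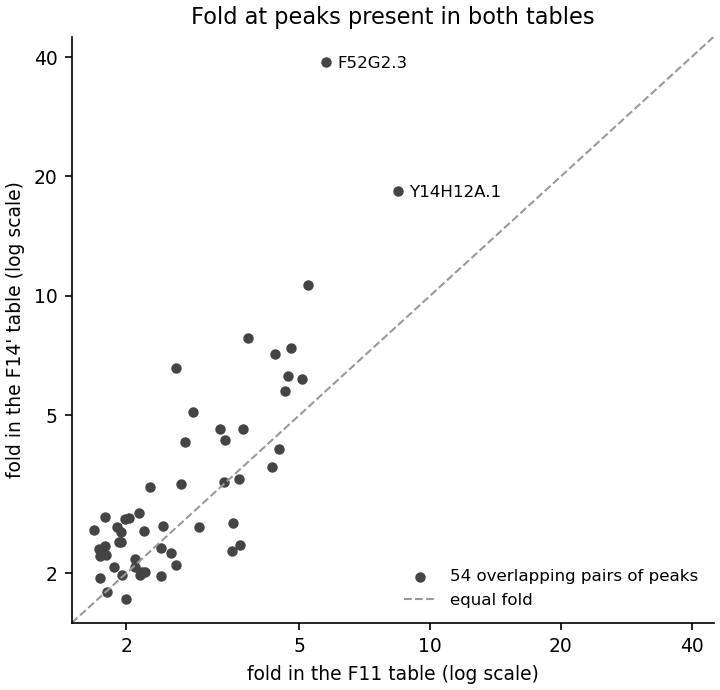
Fold in the F14' table (y axis, log scale) against fold in the F11 table (x axis, log scale) at the 54 overlapping pairs of peaks, with the line of equal fold. F52G2.3 (5.78 and 38.9) and Y14H12A.1 (8.46 and 18.4) stand highest in F14'.

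By gene, 42 genes of the reference table had a peak in both lists, against 1.59 for independent lists of 89 and 837 genes among 46926, and a mean of 2.01 in random lists matched on gene length. F52G2.3 and Y14H12A.1 led by mean rank of fold, followed by gmeb-3 (folds 4.79 in F11 and 7.39 in F14'), Y51A2B.16 (3.81 and 7.83), mys-2 (4.72 and 6.27) and clec-135 (4.63 and 5.76). Genes for channels and membrane proteins among the first 20 were best-2, a bestrophin (2.60 and 6.57), acd-5, a DEG/ENaC channel (2.85 and 5.11), stim-1 (3.35 and 3.40) and irld-1 (2.27 and 3.29). The PI3-kinase gene age-1 of the insulin pathway, whose loss lengthens life, had a promoter peak in both (chromosome II, 11527550 to 11528670 in F11; folds 3.53 and 2.68). Its F11 peak held 378 tags and had a score of 58.1 and an FDR of 100%. The remaining genes were M01E5.1, Y75D11A.1, ZC190.9, T13G4.1, Y54B9A.1, Y71A12B.12, Y73B6BL.47, T20H12.1 and Y54F10AM.8, with F11 folds between 2.14 and 4.49. With peaks within 1 kb of a start, 5 of 15 F11 genes were shared, and with peaks within 3 kb, 24 of 59. Without the 22 peaks that lie nearer to the start of another gene, 41 of 80 were shared.

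Among the gene lists fixed before the data were examined, innate immunity genes stood out in F14', with 20 of 382 members assigned a peak against 8.60 in length-matched random lists (percentile 99.96 of 10000). They lay in 23 peaks, and 16 of these genes were C-type lectin genes, including clec-9 (fold 7.49), clec-135 (5.76) and clec-223 (5.49). C-type lectin genes made up 264 of the 382 members, and their 16 stood against 6.02 in random lists. The excess of the list thus lay mainly in this gene family, and the remaining members were not ranked by themselves. The p38 pathway adaptor gene tir-1 (6.99, peak centre at -6150 bp from its start) was also assigned a peak. The F-box, MATH and BTB families had 20 of 505 members (percentile 99.4), led by fbxa-55 (27.9), fbxa-190 (12.7), fbxa-208 (5.64) and fbxa-75 (4.61). The fbxa-55 peak was centred 4616 bp from its start. Homeobox and developmental factor genes had 8 of 121 (percentile 99.2), with ceh-90 (4.27), vab-7 (2.64), ceh-84 (2.27) and ceh-27 (2.14) highest. Chemoreceptors had 48 of 1629 (percentile 98.1), among them srh-246 (10.7), str-221 (9.36), sre-47 (7.24) and srz-32 (4.63). The H3K4 methylation machinery had 2 of 17 (percentile 95.5), namely set-16 (2.83) and ash-2 (2.57), both parts of H3K4 methyltransferase complexes. With only the nearest gene per peak counted, this list fell to percentile 32.4, so its rank depends on how peaks are assigned to genes. Of 50 list percentiles computed over both tables, 5 lay above 95, where the nominal chance number is 2.5. Counts are small and some members share a peak, so the true chance number may differ. At a score of at least 100, innate immunity stayed at percentile 99.99, while F-box families fell to 85.6, homeobox genes to 79.6, chemoreceptors to 11.9 and the H3K4 machinery to 41.9. With peaks within 3 kb of a start, F-box families fell to 92.8, and the other lists named above stayed above the 95th percentile. With random lists matched on chromosome, gene order and gene length, F-box families fell to 53.8 and chemoreceptors to 95.6, and matched on chromosome and gene order without length they fell to 56.3 and 83.2.

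**Figure D4:**
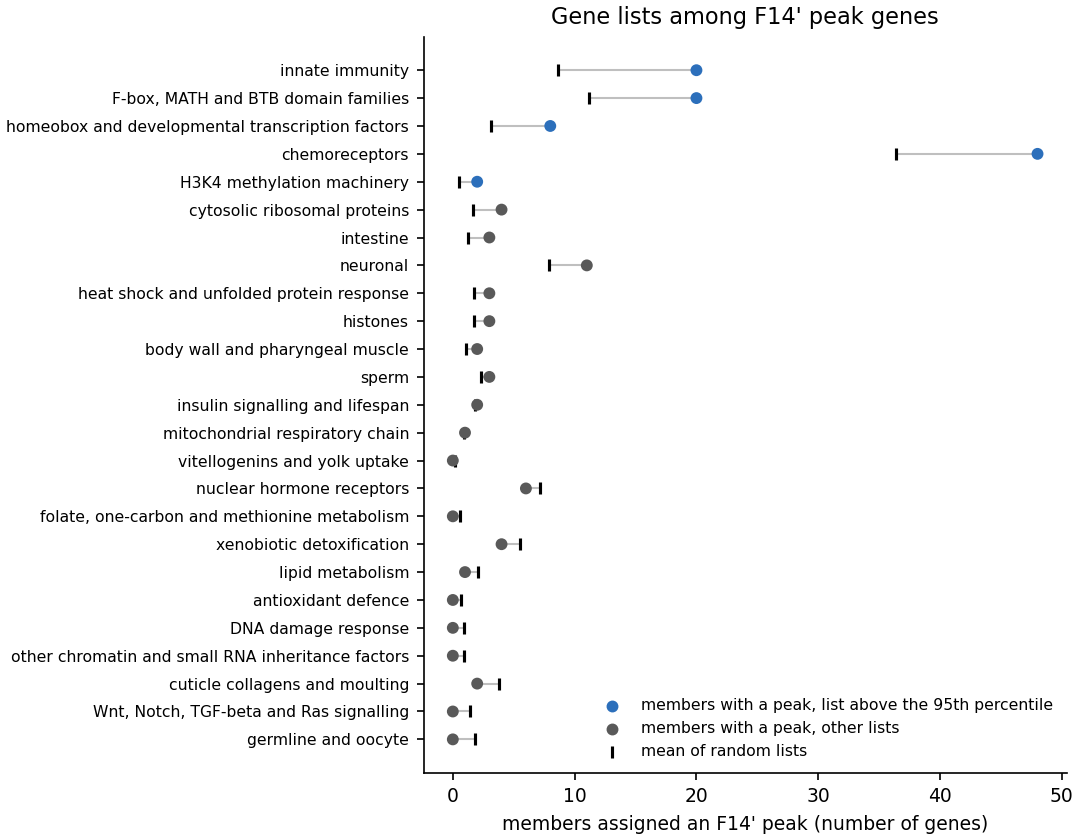
Members of each of the 25 gene lists with an F14' peak (x axis, number of genes; points) and the mean number in length-matched random lists (vertical bars), with lists ordered by percentile (y axis). Innate immunity has 20 members with a peak against 8.60.

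The other lists did not stand above the 95th percentile in F14' in length-matched random lists. Neuronal and ribosomal protein genes passed it with random lists matched on chromosome, gene order and length (96.7 and 97.8), without the length matching (98.9 and 95.7) and with unmatched lists (98.7 and 96.8), and ribosomal protein genes also within 3 kb of a start (96.6). Intestinal genes passed it with unmatched lists (95.4) and at a score of at least 100 (99.4). Ribosomal protein genes had 4 of 78 members with a peak (percentile 94.7; rps-19, fold 2.97; rpl-1, 2.66), and intestinal genes 3 of 55 (vha-19, 17; asp-19, 4.96; vha-1, 2.44). Neuronal genes had 11 of 299, with lgc-26 (8.99), lgc-35 (6.19) and glr-5 (5.93) highest. Heat shock and unfolded protein response genes had 3 of 69 (xbp-1, 2.70; dnj-19, 1.89; hsp-1, 1.89), histones 3 of 81, muscle genes 2 of 40 (unc-68, the ryanodine receptor gene, 9.89; myo-1, 1.76) and sperm genes 3 of 101 (ssp-36, 7.27; msp-113, 5.23). Xenobiotic detoxification genes had 4 of 226 (percentile 27), with gst-11 (7.59), ugt-24 (7.35), haf-7 (6.99) and pgp-14 (1.89). Insulin and lifespan genes had 2 of 71 (age-1, 2.68; eat-2, 2.21). Nuclear hormone receptors had 6 of 288, collagens and moulting genes 2 of 179, and lipid metabolism (lbp-9, 2.44) and the respiratory chain (T20G5.14, 13.1) 1 member each. Some of the named peaks lay far from the assigned start, at -17436 bp for unc-68, -16729 bp for haf-7, -11561 bp for rps-19 and 6917 bp for T20G5.14. Folate and one-carbon metabolism, antioxidant defence, DNA damage response, vitellogenins, germline and oocyte genes, other chromatin and small RNA factors, and Wnt, Notch, TGF-beta and Ras signalling had 0 members with a peak in either table.

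In F11, no list passed the 95th percentile with all peaks and length-matched lists, and 19 of the 25 had 0 members with a peak. Chemoreceptors had 8 members (percentile 83.0, and 99.3 with unmatched lists), with srh-245 (5.25), srh-292 (2.24), srj-9 (2.17) and sra-20 (1.94) highest. F-box, MATH and BTB families had 4 (percentile 94.0; 99.1 with unmatched lists, 96.2 among protein-coding genes, 95.2 without peaks nearer to another gene, 57.8 matched on chromosome and gene order and 45 matched on these and length), namely fbxb-5 (2.02), fbxc-30 (1.79), math-18 (1.79) and fbxb-54 (1.65). Innate immunity had 2, clec-135 (4.63) and clec-70 (1.86). Insulin and lifespan genes (age-1, 3.53), neuronal genes (lgc-30, 1.74) and nuclear hormone receptors (nhr-259, 1.96) had 1 each.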

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

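Settings with a score of at least 50, without peaks assigned to piRNA genes alone, with the nearest gene per peak, without peaks nearer to the start of another gene, with placement within 500 kb and with matching on position, with or without length, were chosen after seeing the data. Of the settings tried on the main results, 37 stayed within 1.5 times of the main count or within its interval and 27 moved. Stricter scores and limits leave fewer peaks by construction. F11 kept 27 peaks at a score of at least 100, 51 at 50, 33 above the median fold of both tables and 1 at an FDR of at most 5%. F14' kept 239, 393 and 331, and no FDR setting could be run. Merging within 1 kb (94 and 628) and leaving out the mitochondrial chromosome (95 and 639, as neither table lists peaks there) changed little. At a score of at least 100 the promoter share was 29.6% in F11 and 49.8% in F14', the share in the middle 33% was 22.2% and 24.3%, and F14' had 15.1% on X and 20.5% on V. Over covered base pairs the F14' promoter share was 51.9%. With the 95 F14' peaks of smallest p it was 35.8%, with 27.4% in the middle and 17.9% on X. Shared peaks numbered 22 of 27 F11 peaks at a score of at least 100, against a random placement mean of 0.383. With equal numbers of peaks they numbered 12 of 95, against a mean of 0.514, and under the other overlap rules 49, 54 and 52. Shared genes numbered 5 of 15 F11 genes within 1 kb, 24 of 59 within 3 kb and 16 of 24 at a score of at least 100. Length-matched random lists had means of 0.157, 1.06 and 0.216. For F11, 2 lists passed the 95th percentile against unmatched random lists (chemoreceptors, F-box), 1 among protein-coding genes and 1 without peaks nearer to another gene (both F-box). For F14', 8 passed against unmatched lists and 2 at a score of at least 100 (innate immunity, intestine). Innate immunity stayed above in all 8 settings, homeobox genes in 7, chemoreceptors and the H3K4 machinery in 6 and F-box genes in 4. Other causes were not tested. Unknown library totals and 1 library per group limit all values.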

Other observations

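The screen of name prefixes added groups outside the fixed lists, and some within them. In F14' the 5S rRNA genes led, with 13 of 21 rrn genes assigned a peak, but from 3 peaks on chromosome V, the strongest from 17114960 to 17116754 with 2037 tags and a fold of 3.52. Next stood the C-type lectin clec genes, with 16 of 264 (percentile 99.97), whose members are in the innate immunity list. They were followed closely by sdz genes, a group regulated by the transcription factor SKN-1, with 5 of 35 members in 5 separate peaks (99.965), led by sdz-19 (fold 4.21). The ceh (99.7) and fbxb genes (99.5), both in fixed lists, came after these, and gtnt genes had 5 of 58 (99.3). Within the fixed neuronal and chemoreceptor lists, neuropeptide-like nlp genes had 5 of 78 (98.2) and srw genes 8 of 145 (98.8). In F11 long intergenic noncoding genes had 3 of 170 (percentile 99.4), namely linc-64, linc-98 and linc-113. The linc-98 peak is centred 2 bp from the start of C31G12.5 and 2793 bp from its own, and without peaks nearer to the start of another gene, a setting chosen after the result was seen, 2 remained (96.0). Of 106 prefixes, 13 passed the 95th percentile in F14' and 4 in F11, where the nominal chance number is 5.3 for each.

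Of the tests below, those on library depth and on a common control background were chosen after the result was seen, as were the comparison with own tags over 10 kb, and the split by list and the length matching of the position test, which had been set as 1 test over 3 lists.

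The larger number of peaks in F14' (639 against 95) may come from a different background in its peak calling. A several-fold deeper library alone, with the mark unchanged, is argued against, since F14' tags per kb were a median of 1.03 times those of F11 at the 54 overlapping pairs, and 1.29 times or less at 90% of them. A common control background with 1 scale factor needs 1 constant ratio of F14' to F11 background (from tags and p). The ratio had a median of 0.631 and was at most 0.729 at the 7 pairs whose F11 background lay over 25% above own tags, such as mys-2 and best-2. At the other 37 pairs under the ceiling its median was 0.960 (0.824 or more at 90%). A ratio that varies argues against such a background. Yet the 7 pairs were picked on their F11 background, the denominator of the ratio. That choice by itself favours low ratios, which weakens the argument. A call without a control library remains a candidate explanation: at 97.1% of 35 tag-rich F14' peaks (exact 95% interval 85.1 to 99.9%) the implied background lay within 25% of their own tags over 10 kb, against 4 of 11 in F11. That density was built from peak tags and the median background, as tags outside peaks are not listed. The 69 F14' peaks at the ceiling of the score, against 1 in F11, could not be compared, so these shares cover only peaks under it. A test set beforehand, that no p be smaller than own tags over 10 kb allow, could hardly fail for narrow peaks and decides nothing, and a true rise after exposure ended stays untested.

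Few peaks lay in the middle 33% of the chromosomes, where C. elegans has many of its conserved genes. Regions of high tag density alone are argued against as the reason, since F14' peaks under the median density had a share of 12.9% there (9.38 to 17%). Marginal peaks alone are argued against by the share of 24.3% (19 to 30.2%) at a score of at least 100, yet the weaker peaks had 13.2% and the interval of the 95 strongest (18.7 to 37.5%) held the share expected from length. The deficit may therefore come mainly from weak peaks, and repeats or mappability in the chromosome arms were not tested. No biological explanation was tested.

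Innate immunity, F-box and homeobox genes ranked high among F14' peak genes, and position on the chromosomes could account for such a ranking. With random lists matched on chromosome, 10 bins of gene order and gene length, F-box genes fell to percentile 53.8, as position alone predicts. Innate immunity stayed at 99.8 and homeobox genes at 99.8, which argues against position alone for these. The homeobox list left the top 5% at a score of at least 100 (79.6), and innate immunity did not (99.99). A link of the C-type lectin genes to earlier SMX exposure is a hypothesis that stays untested, as the F14' background was not shown to be the control.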
